A study of Arabidopsis thaliana with 6 samples.

How the data were processed

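Small RNA was sequenced from whole Arabidopsis thaliana seedlings of the Col-0 accession (WT) and of the hd2b hd2c double knockout, with 3 libraries per genotype. HD2B and HD2C are plant-specific histone deacetylases. Plants grew at 22 °C with 16 h of light and 8 h of dark, and the treatment label of these 6 libraries is normal, so none of them was heated. RNA was isolated with Trizol and libraries were made with the NEBNext small RNA kit, per the labels' protocols. The labels number the replicates but do not say whether they are separate cultures, so p-values measure only the spread between these samples, which may be technical.

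Adapters were trimmed with cutadapt and reads were aligned with STAR to TAIR10, per the submitters' processing notes. Versions, and the settings for mismatches and multiple places, are not given in the sources used here. Each deposited file lists alignments of distinct sequences, with position, sequence, strand, length and a value in reads per 1000000 (RPM). The files have no header, so the unit was read from the values. The deposited RPM values sum to 1000000 per library, and a sequence carries its full RPM at each of its places, up to 50 places, so that the values are relative to 1000000 listed alignments and sequences from repeats count several times. Sequences are 18 to 30 nt long. Nuclear sequences were checked against the TAIR10 reference and matched it in 99.6 to 99.8% of the lines sampled. Mitochondrial sequences did not match that reference, so no mitochondrial position is given.

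The smallest common RPM step, taken as 1 alignment, gave 25842160 to 28831520 alignments per library. With each sequence counted once, WT libraries 1, 2 and 3 held 11726763, 11864046 and 11957822 reads, and hd2b hd2c libraries 1, 2 and 3 held 11476148, 11001095 and 11253516. Between 99.97 and 99.98% of values in a file were whole multiples of the step (within 0.01 of a step, or 1e-05 of the value where that is larger) and the others were not, so the values were not treated as whole reads and the count model that had been foreseen for countable files was not used. Listed alignments outside structural RNA in the nucleus, with a sequence counted at each of its places, numbered 5140797 to 10272111 per library. The lowest number was in hd2b hd2c library 2 and the highest in WT library 3. RPM values are relative, so a change in abundant structural RNA fragments moves all other values.

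RPM was summed in 238296 nuclear windows of 500 bp and, as mean density per 500 bp, over annotated loci. Windows that overlap annotated rRNA, tRNA, snRNA or snoRNA genes were then left out. The pseudocount was 0.0716 RPM, the 25th percentile of non-zero window values, and windows or loci with a mean of at least 5 pseudocounts (0.358 RPM) were tested. Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) on log2(RPM + pseudocount), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of low windows. The robust fit gave windows an infinite prior for the variance, so that the spread of a window in its own 3 and 3 libraries hardly enters its p-value, and very small adjusted p-values reflect the trend over all windows. The annotation used (RefSeq, TAIR10.1, with the TAIR10 sequence) has no transposable element features. The test planned on transposable elements was therefore run on loci that RefSeq calls pseudogenes, many of which are transposable element genes, and the 8 lists of element families among the 26 fixed lists were not run. The 25S rRNA is not annotated there either, so the rDNA region was taken as within 10 kb of annotated nuclear rRNA genes, a definition made after the values were seen.

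Shares by feature class and by length and the ratio of pericentromere to arms were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. The pericentromere was within 3 Mb of 15, 3.6, 14, 4.0 and 12 Mb on chromosomes 1 to 5. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The groups, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The naming rule took, per test, the 5 highest and 5 lowest fold changes among calls whose libraries did not overlap between genotypes and whose mean was at least 20 pseudocounts (1.43 RPM). Where none passed, it took the 3 with the smallest p. HD2B, HD2C, AGO4, the TAS genes, the ONSEN copies and the 5 most abundant MIR genes were always included, with up to 4 members per list as examples.

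Simulated data drew all features of a test from a negative binomial with the same dispersion (0.0111 for windows, 0.0183 for loci) and the library shifts. They held no features of unusual spread, so their false calls do not bound those in the real data. With 200 changed features, the window test over 46974 windows called 123 of the 200 and no unchanged window. It recovered 3.70% of windows raised 2-fold and 22.5% of those lowered 2-fold, 100% and 64.5% at 4-fold, and 100% and 73.5% at 8-fold. The test over 7764 loci made 171 calls, 13 of them at unchanged loci. It recovered 32.3% and 70.4% at 2-fold, 100% and 76.7% at 4-fold, and 100% and 86.4% at 8-fold. Pairs of replicate libraries differed beyond counting noise, with chi-square per degree of freedom of 3.11 to 9.66, so none was a second copy of another. Each WT library was set against hd2b hd2c profiles and the other WT libraries over the gained windows by squared differences of square roots of alignments scaled to its total, with signs flipped over windows 100000 times. Alternatives covered the replicate number as a block, library scaling, filter, pseudocount, moderation, window size, feature boundaries and each library left out. Length classes, handling of sequences with several places, the pericentromere ratio without the rDNA region, the scalings and left-out libraries of the list tests and the removal of WT library 3 together with hd2b hd2c library 2 were added after seeing the data.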

Results

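The small RNA of hd2b hd2c seedlings was compared with that of WT seedlings under normal growth conditions, in a series whose title names HD2B, HD2C, the siRNA-binding protein AGO4 and heterochromatin. Each genotype had 3 libraries of 25842160 to 28831520 listed alignments, in which chloroplast sequences made up 11.5 to 14.9% and structural RNA genes together with the rDNA region 52.5 to 64.6%.

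The knocked-out genes themselves gave little small RNA in either genotype. HD2B (AT5G22650, Chr5 7533946 to 7536496) had 0.779 ± 0.116 RPM in WT and 0.621 ± 0.105 RPM in hd2b hd2c (SD, n = 3, exact permutation p = 0.3). HD2C (AT5G03740, Chr5 981859 to 984289) had 0.499 ± 0.239 and 0.614 ± 0.0759 RPM (exact permutation p = 0.6). AGO4 (AT2G27040, Chr2 11536502 to 11542391), which binds 24 nt siRNAs in RNA-directed DNA methylation, had 0.649 ± 0.191 and 0.574 ± 0.226 RPM (exact permutation p = 0.6). All 3 lay under the filter for testing. Small RNA from a gene body does not measure its mRNA, so these values are a weak check of the genotype labels.

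Small RNA accumulated in hd2b hd2c at a limited set of places along the chromosomes. Of 46974 windows tested with limma, 52 rose and 8 fell. Most of the gained windows were nearly silent in WT, with a median of 0.154 RPM against 1.68 RPM in hd2b hd2c and a median log2 fold change of 2.93 (range 1.5 to 4.77). The 24 nt class, which is made by DCL3 in the RNA-directed DNA methylation pathway, had a median share of 52.1% over these windows in the mutant libraries and made up most of the RPM in 29 of the 52, against 47.6% of all nuclear RPM outside structural RNA in hd2b hd2c. By position, 32 of the 52 lay outside annotated genes, 10 in coding exons, 3 in introns, 2 in UTRs, 2 in MIR genes, 2 in other RNA genes and 1 in a pseudogene, and all 8 windows that fell lay outside annotated genes. No such shares over all tested windows are given here. Unannotated sequence held 61.8 ± 2.82% of nuclear RPM outside structural RNA in hd2b hd2c, so these positions are not shown to be particular to the changed windows.

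The strongest gain lay in CYP71A20 (AT4G13310, Chr4 7750305 to 7753210, plus strand), a gene of the cytochrome P450 family. The window at Chr4 7752001 to 7752500 rose from 3.5 ± 2.18 to 87.3 ± 11 RPM (SD, n = 3), a log2 fold change of 4.77 ± 0.34 (SE, limma adjusted p = 1.96e-40). A single 24 nt sequence, ATAACCGGTGTACGTAGATCATGT at Chr4 7752023 to 7752046 on the minus strand, made up 91.7% of it and rose from 3.25 ± 2.00 to 80.1 ± 10.02 RPM. It is antisense to the gene. On the minus strand it starts at the 3′ end of exon 3 of the shorter transcript model, in its UTR. The sequence lies within intron 3 of the longer model.

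**Figure D1:**
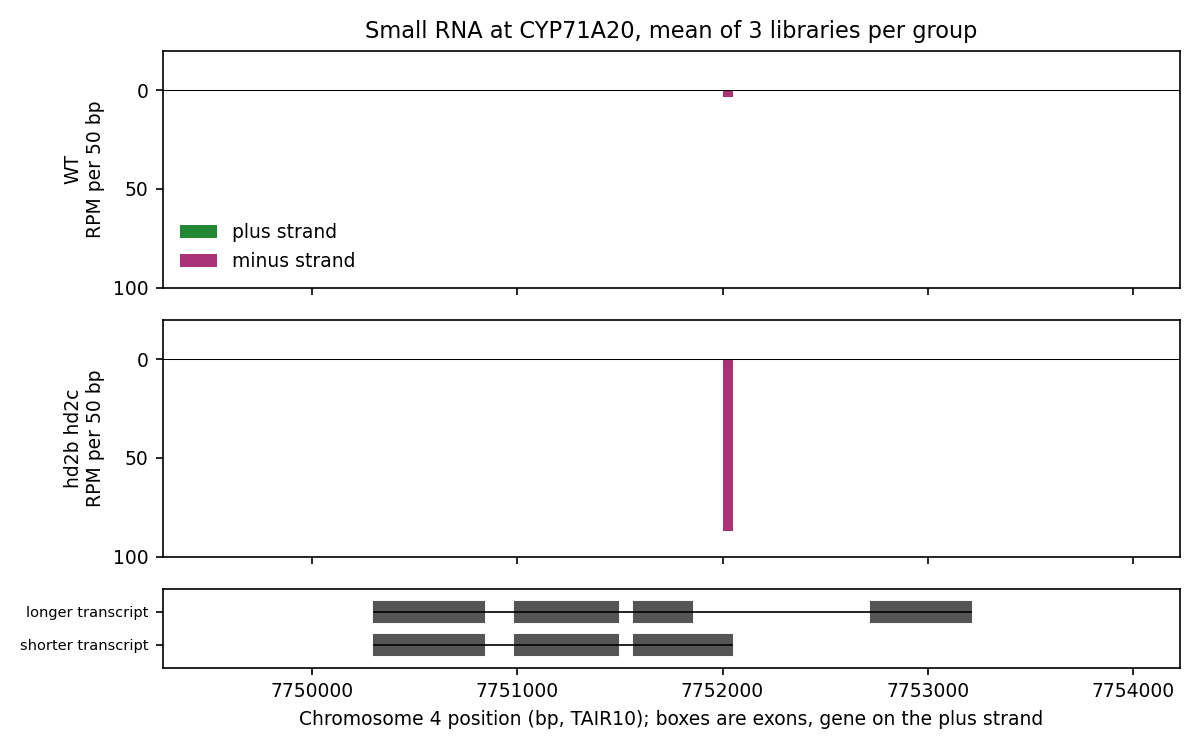
Small RNA along CYP71A20 in WT and hd2b hd2c, as mean RPM of 3 libraries per 50 bp on the plus strand (upward) and minus strand (downward), over chromosome 4 position in bp, with the exons of both transcript models as boxes. The peak on the minus strand is the 24 nt sequence at 7752023 to 7752046, with 3.25 ± 2.00 RPM in WT and 80.1 ± 10.02 RPM in hd2b hd2c (SD).

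The other gained windows that met the naming rule lay outside coding sequence. The window at Chr5 486501 to 487000, 28 bp from MYB3R-5, a MYB transcription factor gene, rose from 1.53 ± 0.975 to 27.3 ± 6.72 RPM (log2 fold change 4.28 ± 0.34). It held 237 sequences, 68.9% of its RPM at 24 nt and 51.1% on the plus strand. This window lies within 2 Mb of the knocked-out HD2C gene, so differences between the lines linked to that mutation stay possible there. At Chr5 17498001 to 17498500, reaching the edge of AT5G43550, values rose from 0.667 ± 0.491 to 10.9 ± 1.39 RPM (4.21 ± 0.35). At Chr1 22261501 to 22262000, at the edge of AT1G60420, they rose from 0.214 ± 0.130 to 4.14 ± 1.09 RPM (3.95 ± 0.38), and at Chr2 16850501 to 16851000, 7 bp from the DREB2C gene of the heat and drought-responsive DREB2 family, from 0.131 ± 0.104 to 2.81 ± 0.688 RPM (3.92 ± 0.40). Among the windows that fell, 2 met the rule. The window at Chr5 24100501 to 24101000, at the edge of the subtilase gene SBT5.4, fell from 5.79 ± 1.81 to 2.22 ± 1.19 RPM (log2 fold change -1.44 ± 0.34, limma adjusted p = 0.0233). The window at Chr2 15851001 to 15851500, 226 bp from AT2G37840, fell from 7.13 ± 1.37 to 2.83 ± 1.02 RPM (-1.36 ± 0.34, limma adjusted p = 0.0487).

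**Figure D2:**
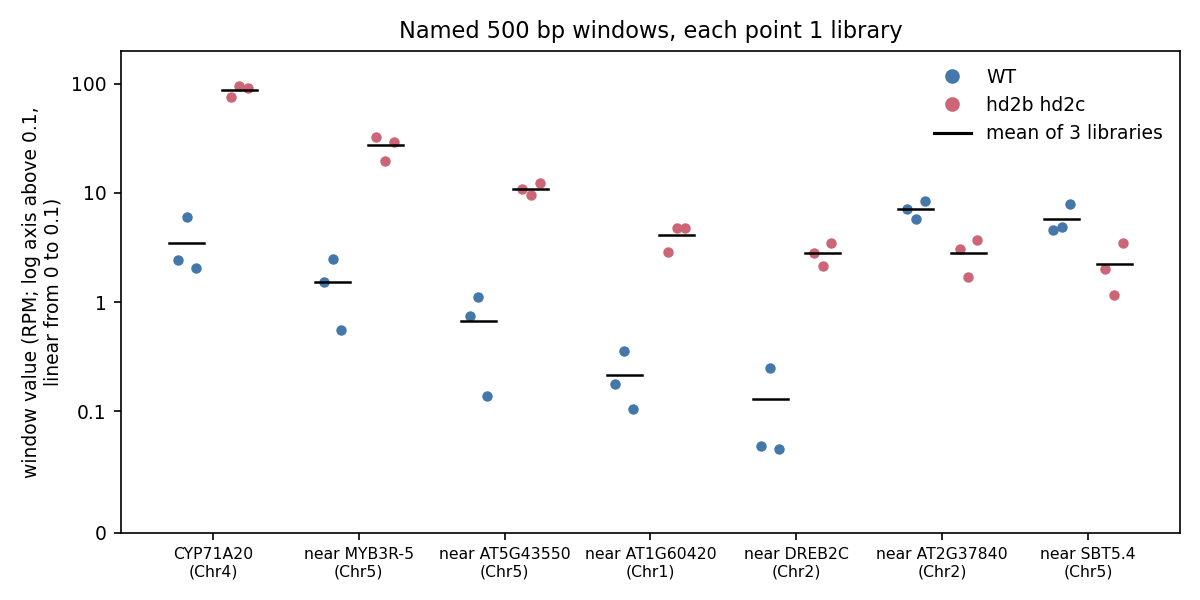
RPM in the named 500 bp windows, with each point 1 library and black lines the mean of 3 libraries per genotype, on a log axis above 0.1 RPM and a linear one below. The naming rule takes only windows whose libraries do not overlap between genotypes. By that rule all hd2b hd2c libraries lie above all WT libraries in the 5 gained windows, and all lie below in the 2 windows that fell.

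At an unadjusted p under 0.05, 387 of the 46974 windows were higher and 1285 lower, together a smaller share than the 0.05 expected with no change. The median log2 fold change over all windows was -0.17, a shift of the whole distribution. WT library 3 lay 0.43 above the mean of the libraries by its median window and hd2b hd2c library 2 lay at -0.43, and without either the median log2 fold change was 0.00 (WT library 3 left out) or 0.01 (hd2b hd2c library 2 left out). With libraries scaled to a common median, 51 windows rose and 20 fell, and with scaling to the nuclear total outside structural RNA 55 rose and 19 fell. The calls at CYP71A20, near MYB3R-5 and near AT5G43550 ended under both scalings (limma adjusted p = 0.263 to 0.459), although their log2 fold changes there were 4.34 to 4.94, because the robust prior then treated them as exceptions and their SE grew to between 0.63 and 0.90. The windows near AT1G60420 and DREB2C passed in all 19 alternatives. The calls of both windows that fell were lost without WT library 1, 2 or 3 or hd2b hd2c library 1 or 2 (limma adjusted p = 0.106 to 0.877), with log2 fold changes of -1.04 to -1.59 and SE of 0.32 to 0.43, and the window near AT2G37840 also without hd2b hd2c library 3 (-1.59, limma adjusted p = 0.0546). Both were also lost without the filter, with the stricter filter and without trend and robust moderation (limma adjusted p = 0.0505 to 0.25), with unchanged log2 fold changes. The number of windows that fell was 0 without WT library 1, 3 without WT library 2, 1 without WT library 3 and 5, 3 and 14 without hd2b hd2c libraries 1, 2 and 3, and 0 without the filter or with the stricter filter.

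The gained windows were spread over all 5 chromosomes, with 11, 9, 6, 8 and 18 on chromosomes 1 to 5. Chromosome 5, which carries both knocked-out genes, held 34.6% of them and 21% of the tested windows (Fisher's exact p = 0.025). Only 8 of 52, or 15.4%, lay in pericentromeres, against 62.5% of the tested windows (Fisher's exact p = 3.63e-12). Neighbouring windows are not independent, and both tests were chosen after the windows were seen. The gained windows had a WT median of 0.154 RPM, under the filter of 0.358 RPM, so many passed it only through hd2b hd2c. The tested windows are therefore not a matched background, and these p-values do not show where gains are favoured. Before the filter, 59900 windows outside structural RNA genes lay in pericentromeres and 177410 in arms. The groups did not overlap in 51 of the 52, as in 7.44% of all tested windows, where chance gives 10%. In 38 of the 52 the mean was under 1.43 RPM.

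**Figure D3:**
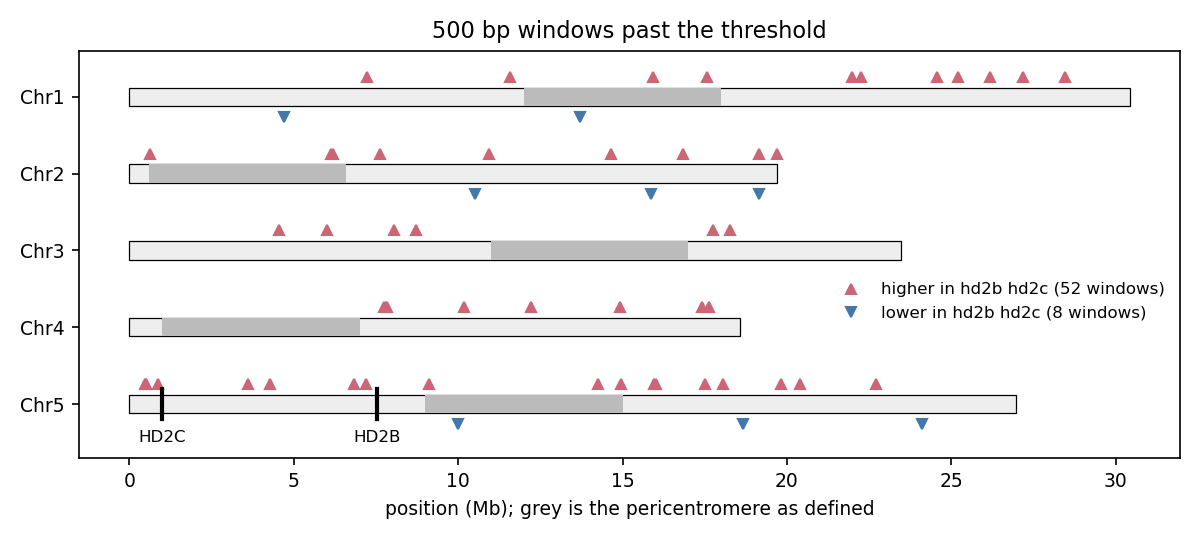
Positions in Mb of the 52 windows that rose (triangles pointing up) and the 8 that fell (pointing down) on the 5 chromosomes, with pericentromeres in grey and HD2B and HD2C marked. Of the windows that rose, 18 lie on chromosome 5 and 8 in pericentromeres.

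Pericentromeric heterochromatin as a whole did not differ between the genotypes beyond the spread of the libraries. Mean window RPM in pericentromeres was 4.64 ± 0.337 in WT and 4.33 ± 0.193 in hd2b hd2c (SD, n = 3, exact permutation p = 0.3), and in arms 1.54 ± 0.0865 and 1.44 ± 0.0383 (exact permutation p = 0.1, the smallest possible). The arm libraries did not overlap there, but they did with the 2 Mb boundary, without the highest 1% of windows and without the rDNA region (exact permutation p = 0.2 to 0.6). Without the rDNA region the means fell to 2.37 ± 0.551 and 2.09 ± 0.440 RPM in pericentromeres and 0.819 ± 0.155 and 0.725 ± 0.128 RPM in arms. The log2 ratio of pericentromere to arms was 1.59 ± 0.02 in WT and 1.59 ± 0.03 in hd2b hd2c (exact permutation p = 0.9), a difference well under the spread between libraries.

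Loci annotated as pseudogenes, which include many transposable element genes, changed at 2 of 2842 tested. AT4G13470 (Chr4 7827973 to 7829482) rose from 0.215 ± 0.186 to 3.10 ± 0.605 RPM (log2 fold change 3.04 ± 0.34, limma adjusted p = 4.77e-06), and AT3G14500 (Chr3 4866406 to 4866822) fell from 1.25 ± 0.25 to 0.399 ± 0.149 RPM (-1.54 ± 0.30, limma adjusted p = 0.0162). Neither met the naming rule, nor did AT5G29090, next by p, with 4.78 ± 1.04 and 2.05 ± 0.800 RPM (-1.23 ± 0.32, limma adjusted p = 0.268). Unadjusted, 11 were higher and 20 lower, and adjusted over the list alone the counts were 1 and 1. Both calls ended under either other scaling (limma adjusted p = 0.168 to 0.265), with log2 fold changes of 3.12 and 3.10 at AT4G13470 and -1.47 and -1.39 at AT3G14500, as the prior degrees of freedom for loci went from 25.1 to 2.84 and 2.50. The count was 6 without WT library 2 (1 higher, 5 lower), 4 without WT library 3 (3 higher, 1 lower) and 6 without hd2b hd2c library 3 (1 higher, 5 lower). The AT4G13470 call also ended with the pseudocount divided by 4, and the AT3G14500 call without trend and robust moderation. Without the filter 2 loci were called, 1 of them among these 2.

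The ONSEN copies, heat-responsive COPIA78 retrotransposons, showed no call. All 8 had negative log2 fold changes with a median of -0.15, but with scaling to the nuclear total the median was 0.02 and 1 was negative. Summed over the copies, RPM was 196 ± 45.8 in WT and 178 ± 46.8 in hd2b hd2c (SD, n = 3). AT1G11265 had 26.8 ± 6.37 and 24.1 ± 6.46 RPM, AT3G61330 26.2 ± 6.32 and 23.7 ± 6.66, AT5G13205 22.6 ± 5.15 and 21.1 ± 5.45, and AT1G58140 26.3 ± 6.31 and 24 ± 6.26. AT1G48710 had 25.2 ± 5.59 and 22.9 ± 5.86 RPM, AT3G59720 25.1 ± 5.87 and 22.4 ± 6.09, AT1G21945 25.8 ± 5.69 and 23.1 ± 5.77, and AT3G32415 17.8 ± 4.55 and 17.0 ± 4.26. The copies share sequences, so their values are not independent. Limma called 0 of 8 over all loci and adjusted over the list alone, with 0 also at an unadjusted p under 0.05.

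Protein-coding genes rose at 4 of 2839 tested, and none fell (limma, unadjusted 74 higher and 43 lower). Summed over the gene, CYP71A20 rose from 3.90 ± 2.14 to 87.7 ± 11 RPM (log2 fold change 4.45 ± 0.33, limma adjusted p = 3.55e-10). The single 24 nt antisense sequence gave 80.1 ± 10.02 RPM of this in hd2b hd2c, so the rise was not spread along the gene. The other 3, named after their values were seen since their mean densities per 500 bp (0.85, 0.451 and 0.653 RPM) lay under the 20 pseudocounts of the rule, were, in RPM summed over the gene, AT5G36200 (1.44 ± 0.324 to 6.01 ± 0.857 RPM, log2 fold change 1.86), AT3G17530 (0.543 ± 0.0912 to 2.02 ± 0.629 RPM, 1.54) and AT4G27657 (0.448 ± 0.0485 to 1.42 ± 0.249 RPM, 1.45). Adjusted over the list alone the counts were 4 and 0. Outside these classes AT5G07575 (log2 fold change 3.34) and AT2G06995 (3.46), both annotated as other RNA genes, rose as well. Under either other scaling 0 protein-coding genes were called, with CYP71A20 at a log2 fold change of 4.52 or 4.61 (limma adjusted p = 0.057 and 0.0713), AT5G36200 at 1.93 or 2.01, AT3G17530 at 1.61 or 1.68 and AT4G27657 at 1.53 or 1.61. The AT2G06995 call ended there as well, with 3.53 and 3.55 (limma adjusted p = 0.102 and 0.0713). Without the filter the calls of AT5G36200, AT3G17530 and AT4G27657 ended (limma adjusted p = 0.0531, 0.183 and 0.153), as did those of AT3G17530 and AT4G27657 without trend and robust moderation (limma adjusted p = 0.112 and 0.0826). The count was 11 without WT library 1 (10 higher, 1 lower), 13 without WT library 2 (12 and 1), 8 without hd2b hd2c library 2 (7 and 1) and 12 without hd2b hd2c library 3 (6 and 6). The calls of AT3G17530 and AT4G27657 were lost without hd2b hd2c library 1 (limma adjusted p = 0.282 and 0.0731).

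Among microRNA genes MIR843 (AT3G48057, Chr3 17742098 to 17742302) rose from 10.9 ± 1.16 to 38.7 ± 16.1 RPM (log2 fold change 1.75 ± 0.28, limma adjusted p = 1.03e-03). Its most abundant sequence, TTTAGGTCGAGCTTCATTGGA at Chr3 17742147 to 17742167 on the plus strand, had 4.91 ± 0.261 RPM in WT and 16.2 ± 8.45 in hd2b hd2c. The 5 most abundant MIR genes did not pass. MIR161 had 3333 ± 232 and 3424 ± 483 RPM, MIR319c 1582 ± 26.4 and 1482 ± 288, MIR158a 677 ± 14.4 and 628 ± 158, and MIR398b and MIR398c, which share their sequences, each 1873 ± 790 and 1491 ± 461. Of 238 MIR genes 1 rose and 0 fell (limma, unadjusted 4 higher and 18 lower). Adjusted over the list alone, MIR838 also fell, from 0.342 ± 0.0669 to 0.133 ± 0.0505 RPM (log2 fold change -1.23, adjusted p = 0.0404). MIR838 overlaps another gene. The MIR843 call ended under either other scaling, with log2 fold changes of 1.83 and 1.93 (limma adjusted p = 0.265 and 0.33), and without the filter or without trend and robust moderation, with 1.75 in both (limma adjusted p = 0.164 and 0.082). The count of MIR genes was 3 without WT library 1 (2 higher, 1 lower), 4 without WT library 2 (2 and 2) and 2 without WT library 3 (1 and 1). It was 2 without hd2b hd2c library 2 (1 and 1) and 8 without hd2b hd2c library 3 (2 higher, 6 lower).

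**Figure D4:**
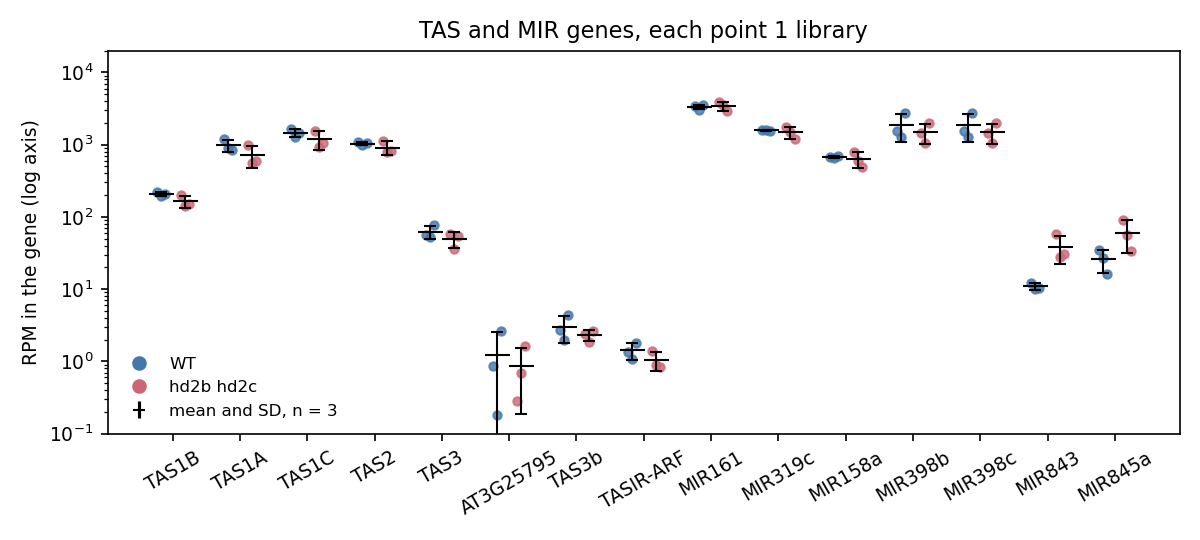
RPM in TAS genes, the 5 most abundant MIR genes, MIR843 and MIR845a, with each point 1 library and black marks the mean ± SD of 3 libraries, on a log axis. MIR843 rises from 10.9 ± 1.16 to 38.7 ± 16.1 RPM, and the lower SD bar of AT3G25795 in WT runs below the axis.

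Trans-acting siRNA precursors, which phased 21 nt siRNAs are cut from, were lower in mean RPM in hd2b hd2c, with no member past the threshold. Mean RPM in WT and hd2b hd2c was 983 ± 197 and 714 ± 241 at TAS1A, 207 ± 12.4 and 165 ± 33.1 at TAS1B, 1473 ± 182 and 1180 ± 343 at TAS1C and 1035 ± 52.9 and 911 ± 198 at TAS2. It was 61.9 ± 12.5 and 49.3 ± 11.7 at TAS3, 3.02 ± 1.25 and 2.32 ± 0.414 at TAS3b, 1.41 ± 0.368 and 1.03 ± 0.294 at TASIR-ARF and 1.24 ± 1.29 and 0.861 ± 0.677 at AT3G25795. All 8 log2 fold changes were negative, with a median of -0.34, and -0.17 with scaling to the nuclear total. The camera test at the preset correlation placed the TAS genes below other loci (adjusted p = 6.02e-03), and with an estimated correlation it did not (adjusted p = 0.83). The call was also lost without WT library 1 or hd2b hd2c library 3 (camera adjusted p = 0.0706 and 0.0911), where the medians were -0.32 and -0.35, and the median was -0.25 without WT library 3 and -0.18 without hd2b hd2c library 2.

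Of the 14 lists tested with camera, 5 passed at the preset correlation and 0 with an estimated one, where each of these 5 had an adjusted p = 0.83. Besides the TAS genes, these were the conserved miRNAs, with 64 of 74 members negative and a median of -0.21 (camera adjusted p = 2.03e-05), the auxin and growth miRNAs, with 27 of 31 negative and a median of -0.21 (camera adjusted p = 6.49e-04), and the silencing feedback miRNAs, from families that target DCL1, AGO1 or AGO2 and from MIR838, which lies within the DCL1 gene, with 6 of 6 negative and a median of -0.30 (camera adjusted p = 6.02e-03). Structural RNA genes lay above other loci, with 551 positive and 381 negative and a median of 0.07 (camera adjusted p = 1.44e-04, and 0.0684 with scaling to the nuclear total). In the conserved list MIR169e had 1.52 ± 0.624 and 0.634 ± 0.168 RPM, and in the auxin and growth list MIR159a had 704 ± 120 and 518 ± 151 RPM in WT and hd2b hd2c. MIR168a, whose miRNA targets AGO1, had 41.6 ± 6.06 and 33.5 ± 13.4 RPM. With scaling to the nuclear total the medians were -0.04 for the conserved, -0.04 for the auxin and growth and -0.13 for the silencing feedback miRNAs. WT library 3 and hd2b hd2c library 2, the libraries that stood apart by their median window, bore on these medians. The median of the conserved miRNAs was -0.07 without WT library 3, -0.03 without hd2b hd2c library 2 and 0.09 without both, where all loci had 0.06, 0.07 and 0.20, and the camera call held in each at the preset correlation (adjusted p = 5.83e-04, 0.0129 and 0.0321) and in none with an estimated correlation (adjusted p = 0.815, 0.981 and 0.764). Without hd2b hd2c library 2 the auxin and growth, silencing feedback and structural RNA calls were lost (camera adjusted p = 0.105, 0.164 and 0.164), the first 2 also without hd2b hd2c library 3 (0.277 and 0.054) and the structural RNA call without WT library 3 (0.0959). Without both libraries that stood apart the silencing feedback call was lost (camera adjusted p = 0.166) and structural RNA genes lay below other loci at the preset correlation (camera adjusted p = 3.14e-06), but not with an estimated correlation (adjusted p = 0.764). The photosynthesis mRNAs passed in that fit too, with 10 of 10 negative and a median of -0.18 (camera adjusted p = 4.95e-05, and adjusted p = 0.764 with an estimated correlation).

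The other 9 lists did not pass with camera. Their median log2 fold changes were -0.15 for the ONSEN copies, -0.05 for 4 silenced loci that include FWA, -0.07 for 7 copper miRNA genes, -0.46 for 12 phosphate and sulfate miRNA genes, -0.07 for 12 juvenile phase and -0.19 for 5 adult phase miRNA genes. They were -0.16 for 8 defence and phasiRNA miRNA genes, -0.22 for 4 pollen and seed miRNA genes, whose mean was 0.05, and -0.03 for 10 photosynthesis mRNAs, for which camera pointed up and fry down. Camera adjusted p for these 9 lists was 0.166 to 0.979. Some passed with 1 library left out: the copper and the phosphate and sulfate lists without WT library 1, WT library 2 or hd2b hd2c library 3, the juvenile phase and the defence lists without hd2b hd2c library 1, and the photosynthesis mRNAs without WT library 3 (camera adjusted p = 7.47e-05 to 0.0376). None of the 14 lists passed with an estimated correlation in any fit with libraries left out (adjusted p of at least 0.364). By limma 0 members of any list passed over all loci. Adjusted over the list alone 1 member fell in the silencing feedback list (MIR838) and 1 rose in the pollen and seed list (MIR845a, 25.9 ± 9.33 and 60.6 ± 29.1 RPM), and 0 passed in the other 12. At an unadjusted p under 0.05 the structural RNA list had 46 higher and 17 lower and the conserved miRNAs 1 higher and 7 lower. Fry gave no list a direction (adjusted p = 0.913 to 0.982) or a mixed change (adjusted p = 0.791 to 0.921). The knocked-out genes and the 15 genes of the AGO4 and RNA-directed DNA methylation machinery had 0 members above the filter, the heat shock genes 1 (HSP70, 2.09 ± 0.442 and 2.21 ± 0.512 RPM) and the root mRNAs 2 (PYK10, 4.29 ± 1.01 and 5.93 ± 2.26 RPM, and DR4, 2.03 ± 0.263 and 2.31 ± 0.252 RPM), so these 4 were not tested as lists.

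The length profile of the libraries was broad, with 24 nt the most frequent length. Sequences of 24 nt made up 20.8 ± 2.31% of all RPM in WT and 18.5 ± 2.88% in hd2b hd2c (SD, n = 3, exact permutation p = 0.5), and outside structural RNA in the nucleus 50.3 ± 1.47% and 47.6 ± 3.79% (exact permutation p = 0.4). At 21 nt the share was 7.70 ± 0.299% in WT and 6.97 ± 0.376% in hd2b hd2c, and at 26 nt 9.09 ± 0.564% and 10.7 ± 0.891%. These 2 of the 13 lengths had groups that did not overlap (exact permutation p = 0.1, the smallest possible), and their Benjamini-Hochberg adjusted values cannot reach the threshold. The number of such lengths was 4 without WT library 1 and 4 without hd2b hd2c library 1, where fewer libraries make a lack of overlap more frequent by chance.

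**Figure D5:**
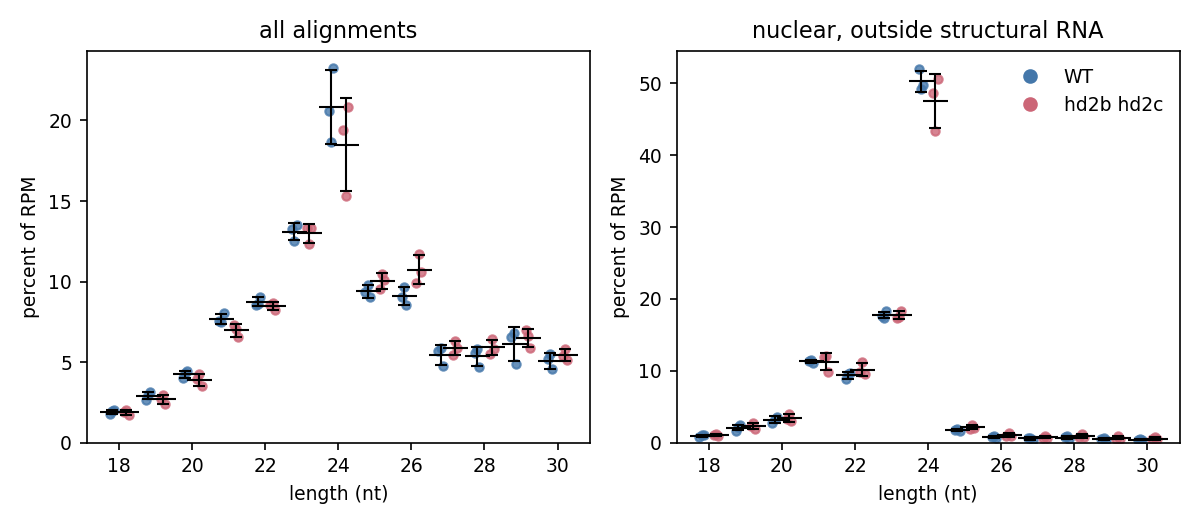
Percent of RPM at each length from 18 to 30 nt, over all alignments (left) and over nuclear alignments outside structural RNA (right), with each point 1 library and black marks the mean ± SD of 3 libraries (blue WT, red hd2b hd2c). At 24 nt the means are 20.8 and 18.5% of all alignments and 50.3 and 47.6% outside structural RNA.

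Shares by feature class did not separate the genotypes. Structural RNA genes held 36.7 ± 3.42% of nuclear RPM in WT and 39.8 ± 1.89% in hd2b hd2c, the rDNA region 30.4 ± 3.17 and 30.5 ± 4.18%, MIR genes 2.11 ± 0.258 and 1.95 ± 0.344%, TAS genes 0.432 ± 0.0467 and 0.352 ± 0.0916%, pseudogenes 4.04 ± 0.826 and 3.94 ± 0.800%, protein-coding genes 4.08 ± 0.391 and 3.94 ± 0.337% and unannotated sequence 21.2 ± 5.02 and 18.4 ± 4.09% (SD, n = 3, exact permutation p = 0.3 to 1). Chloroplast sequences made up 12.4 ± 0.944 and 13.8 ± 1.01% of all RPM (exact permutation p = 0.2) and mitochondrial ones 0.462 ± 0.0448 and 0.510 ± 0.0684% (exact permutation p = 0.4). Of 11 classes, 0 had groups that did not overlap. Outside structural RNA the pseudogene share was 12.3 ± 0.144% in WT and 13.2 ± 0.580% in hd2b hd2c, without overlap (exact permutation p = 0.1). The number of classes without overlap was 2 without WT library 2, 1 without WT library 3, 3 without hd2b hd2c library 1 and 1 without hd2b hd2c library 3.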

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

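Length classes, handling of sequences with several places, the removal of 2 libraries together, the pericentromere ratio without the rDNA region, and the scalings and left-out libraries of the list tests were chosen after the data were seen, and the other alternatives before. The cause of a change was not tested unless stated. The replicate numbers did not qualify as pairs, since the deviations of same-numbered libraries correlated at 0.0856, 0.238 and 0.328, although 6 of 6 libraries correlated best with their own number, which is a hint from the data. With the replicate number as a block 439 windows (101 higher, 338 lower), 6 pseudogene loci (2 higher, 4 lower), 27 protein-coding genes (14 higher, 13 lower), 15 MIR genes (4 higher, 11 lower) and 6 lists passed, the added list being the phosphate and sulfate miRNAs (camera adjusted p = 1.31e-03, and adjusted p = 0.931 with an estimated correlation). The 60 windows became 13 with the filter at 20 pseudocounts, which leaves fewer windows to test, 91 without trend and robust moderation, 25 with 24 nt and 11 with 21 and 22 nt alignments only, and 174 (163 higher, 11 lower) without WT library 3 and hd2b hd2c library 2. Leaving out 1 library at a time gave 44 to 60 windows, of which 0 to 14 were lower.

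The 2 pseudogene loci became 0 under median scaling, nuclear-total scaling, the stricter filter, 24 nt and 21 and 22 nt alignments, and 1 with the pseudocount divided by 4, without moderation by trend, with sequences at 1 place, with values divided by places and without both libraries; single libraries left out gave 2 to 6. The 4 protein-coding genes became 0 under both scalings, with 21 and 22 nt alignments and without both libraries, 1 under the stricter filter, 3 without the filter (1 of them among the 4) and 2 with 24 nt alignments or sequences at 1 place, with 3 to 13 when single libraries were left out. The 1 MIR gene became 0 under both scalings, without the filter, without moderation by trend, in each length class, at 1 place, without both libraries and with the highest position in place of the mean, and 2 under the stricter filter, with 1 to 8 when single libraries were left out. The 5 lists became 0 with an estimated correlation and 2 to 7 with single libraries left out. Classes without overlap were 0, and 1 outside structural RNA (0 to 3 with single libraries left out). Lengths without overlap were 2, at 21 and 26 nt (2 to 4 lengths with single libraries left out). For classes and lengths alike, a lack of overlap is more frequent by chance when a library is left out. Outside MIR and structural RNA genes only 25 nt was without overlap, and 21 and 26 nt were not. The difference of the pericentromere ratio stayed between -0.01 and 0.02. Among single windows and loci, 52 values under planned and 20 under added alternatives lost their call and 22 under planned ones gained one. No named window or called locus reversed its direction under any alternative run, and the other called windows were not followed singly. The structural RNA list passed in the other direction without both libraries (camera adjusted p = 3.14e-06, and adjusted p = 0.764 with an estimated correlation). Overlap of protein-coding genes with transposable elements was tested only as overlap with other annotated loci. Low values limit the calls, since 38 of the 52 windows that rose had a mean under 1.43 RPM.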

Other observations

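All tests in this part were chosen after the results were seen, except the test of carry-over over all 52 gained windows against counting noise, whose prediction was written before its result. The window fits under other scalings and with single libraries left out had been planned, but their use as tests of explanations was chosen afterwards.

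Some gained windows lay close together. On the upper arm of chromosome 5 the windows at 486501, 491501 and 503001 all rose, with log2 fold changes of 4.28, 3.17 and 2.57. They lie within 2 Mb of the knocked-out HD2C gene (Chr5 981859 to 984289), as does the gained window at 856001, so linkage stays open for them. On chromosome 4 the windows at 7752001 in CYP71A20, 7800501 in an intron of the potassium transporter gene HAK5 and 7827501 at AT4G13470 rose by 4.77, 2.12 and 3.62. At HAK5 the libraries of both genotypes overlapped. A window at MIR845a (Chr4 12217501) rose by 1.5 with 98.5% of its RPM at 21 and 22 nt, while the MIR845a gene as a whole did not pass (limma adjusted p = 0.983). A window in AT5G36200, in the pericentromere of chromosome 5, rose from 1.30 ± 0.312 to 5.95 ± 0.859 RPM, and the window near AT4G37500 from 2.11 ± 0.0594 to 6.45 ± 1.46 RPM, of which 0.189% came from sequences at 1 place. Within structural RNA genes the share of 21 and 22 nt fragments was 12 ± 0.25% in WT and 10.5 ± 0.313% in hd2b hd2c, and that of 24 nt 7.43 ± 0.256 and 6.90 ± 0.306%, both without overlap (exact permutation p = 0.1).

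For the gain at 52 windows, fragments of longer transcripts would have the lengths seen at photosynthesis mRNAs, where 24 nt made up at most 11.6%, and the gained windows had a median of 52.1% (quartiles 39.1 and 59.1%), which argues against fragments for most. Of the 4 windows at or under that level, 0 of the 2 at MIR genes had a share of 21 and 22 nt as low as photosynthesis mRNAs (at most 23.5%), while 2 of the 2 others, at the copper-binding protein gene BCB and at AT3G13830, did, so that these 2 may be fragments, although at AT3G13830, a plus-strand gene, 0% of the RPM lay on the plus strand and 1.28% came from sequences at 1 place, which argues against fragments of its own sense transcript. Scaling as the whole cause is argued against by 38 of 52 windows called higher under both other scalings, although the 3 strongest calls ended there with little change in fold, and 46 of the 52 were called from sequences at 1 place alone. Chromosome stretches inherited with the mutated genes could hold other differences between the lines. Within 2 Mb of HD2B or HD2C lay 7 of 52 windows (13.5%, 95% interval 6.68 to 25.3%). Chromosome 5, which carries both genes, held 18 of 52. Either count is too small to explain most of the gain. Near the genes the share exceeded the 2.98% of tested windows (Fisher's exact p = 8.5e-04), but the tested windows are not a matched background. On the arms alone 6 of 44 against 6.42% gave Fisher's exact p = 0.0608. Gained windows between the 2 genes, such as those at Chr5 3615501 and 4282501, were counted as not near. Linkage therefore stays open for windows near and between the genes. A loss of HD2B and HD2C function, which the design names, and differences between plant lines elsewhere in the genome were not tested and remain open.

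The gained windows also carried a trace in WT, which may be carry-over from hd2b hd2c libraries or admixed plants. Against counting noise a single ratio to the mutant over all 52 windows gave a chi-square per degree of freedom of 17.4, 8.45 and 20.6 in WT libraries 1, 2 and 3, where replicate pairs of one genotype differed by 3.11 to 9.66 over 5000 windows, and of 3.24, 1.88 and 5.86 with the spread among the hd2b hd2c libraries allowed for. By a one-sided permutation test over windows, WT libraries 1 and 3 lay farther from every hd2b hd2c profile than from the other WT libraries (highest permutation p = 0.019 and 1.9e-04). This argues against a single ratio as the whole source over the 52 windows together in these libraries. WT library 2 did not lie farther (highest permutation p = 0.775), although its simulated p with the spread allowed for was 0.0069, so in that library carry-over cannot be told apart from WT expression. Both tests over the 52 windows include the one at MIR843, expressed in WT (12.2, 9.98 and 10.6 RPM in WT libraries 1, 2 and 3). Neither was repeated without it, so neither decides on carry-over at the windows nearly silent in WT. Over the 5 named gained windows, picked for large fold changes, the counting-noise values were 5.43, 1.74 and 0.409, which leaves carry-over open there, and WT library 2 was the highest WT library in 5 of these 5, with 7.72% of the mutant level pooled, against 3.76% in WT library 1 and 2.20% in WT library 3.

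The lower median window value in hd2b hd2c, -0.17 on the log2 scale, may come from 2 libraries that stand apart. Without WT library 3 the median was 0.0012, and without hd2b hd2c library 2 it was 0.012. The median library shifts of the genotypes overlapped (exact permutation p = 0.6). No biological explanation was tested for it.

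With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For windows the real split gave 60 calls and the highest other 36, with 1 of the 10 splits as large, and for pseudogene loci 2 calls and 1, with 1 of 10. For protein-coding genes the real split gave 4 calls and the highest other 12, with 3 of 10 as large, and for MIR genes 1 call and 4, with 3 of 10.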
